A study of Caenorhabditis elegans with 2 samples.

How the data were processed

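ChIP-seq was performed, per the labels, on whole L1 larvae of a strain in which grh-1 was tagged by CRISPR with TY1, EGFP and 3xFLAG, with an antibody against GFP and chromatin sheared by sonication. The description in the labels names the antibody as one against GFP, while their antibody field gives grh-1, the name of the tagged protein's gene. There were 2 biological replicates of 1 group, named by the replicate numbers of the labels. The aligner and the peak caller are not given in the sources used here, and the control library was not analysed here.

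The deposited files are peak lists on the build ce11, per the labels. A ranked list per replicate and for the pooled replicates held 99502 peaks for replicate 1, 85197 for replicate 2 and 117774 for the pool, and the authors derived from them the thresholded lists of 1787, 1487 and 2470 peaks. A conservative pooled list held 2389 peaks. The deposited score per peak is a signal value, a score that belongs to its own list and whose scale is not given in the sources used here; it was used to rank and describe peaks. The deposited ranked lists also hold the −log10 of the irreproducible discovery rate (IDR) of each peak and a score made from it. Every thresholded peak had a −log10 IDR of at least 2 in its ranked list, that is an IDR of at most 0.01. In the pooled ranked list 49 further peaks passed that limit and were left out of the thresholded list, for a reason not given in the sources used here. The deposited column for a p-value was not used. A further 16 columns of the pooled ranked tables, which have no header line, were not used. Of the pooled peaks 78.0% had the same width of 344 bp, so widths were not compared. Peaks were called per replicate and on the pooled replicates, so the pooled list is not independent of the replicates' lists. The number of reads is unknown, which limits the precision that can be stated to counting error over peaks and genes.

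Sequences were taken from the reference genome assembly and genes from Ensembl release 115, which share the chromosome lengths of the build; the largest peak end on chromosome V was 20924180, equal to the length of that chromosome. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Only chromosomes I to V and X were used. Replicate overlap needed 1 bp in common and was set against 1000 random placements. The promoter window ran from 1000 bp upstream to 200 bp downstream of a 5′ end. Motifs were searched on both strands in windows of 201 bp centred on the summits, and in windows of the same width centred 500 bp to either side, with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment within each table at 0.05. Summits of neighbouring peaks and overlapping windows are not independent. The correlation of signal value with the palindrome used 100000 resamples. Gene lists were tested against all other protein-coding genes, and with 10000 random lists matched on deciles of upstream intergenic length. The 14 gene lists, the 20 motifs, the tests of replicate overlap, promoter share, motifs, 8-mers, motif rank, gene lists and X, and the rule for named genes were fixed before the data were examined. The distances to 5′ ends, the position of sites within windows, the sites of the genome with their flanking bases, the chromosomes other than X and the summits near grh-1 were added after the data were examined. The rule named 14 genes regardless of peaks, the genes whose promoter window held the 15 highest-scoring summits, up to 4 members of each list with the highest summits, and the highest summit of each position class.

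Alternatives were the conservative list, each replicate's own list, the 1235 highest-scoring peaks, 1 summit per merged region, other windows, backgrounds, sites and overlap rules, and the closing section gives their effect. The steps were tested on simulated data. With nothing planted in 2470 random windows 0 of 32889 8-mers were called. With 20 random 8-mers planted in 99 windows each, 20 of 20 were called. In all 149 8-mers were called there, so counts of 8-mers include shifted forms of the same site. The random windows were set against their own flanks, so calls that follow from a different base composition at real summits were not tested. Of 200 random lists of 70 genes, 3% had p under 0.05, and of 200 lists with a planted share of 30% against 8%, 100% did. These p were not adjusted. Most of the real lists were smaller, had lower shares and were adjusted, so the simulation does not give the power to detect enrichment in them. With 70% of the peaks of replicate 1 copied, 71.3% were found overlapped, since neighbouring peaks overlap each other.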

Results

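The binding of GRH-1, the Caenorhabditis elegans member of the Grainyhead family of transcription factors, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L1 larvae. Grainyhead proteins are known in many animals for their roles in the epidermis and in other epithelia. The animals carried GRH-1 fused to EGFP at the grh-1 locus, and the fusion protein was precipitated with an antibody against GFP. There was 1 group of samples with 2 biological replicates, both from starved, synchronised larvae at an age of 6 h, so the comparisons were those of replicate 1 with replicate 2 and of bound positions with the rest of the genome. The pooled list of peaks that passed the authors' reproducibility threshold held 2470 peaks. The replicates' own lists held 1787 peaks for replicate 1 and 1487 for replicate 2. The number of reads behind the lists was not given in the files used here, so the depth of each replicate is unknown. Intervals on shares are 95% Wilson intervals over peaks or genes and cover counting error only. Coordinates are those of the build ce11.

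The first question was whether the replicates found the same loci. Of the 1787 peaks of replicate 1, 1236 (69.2%, 67.0 to 71.3) overlapped a peak of replicate 2, and of the 1487 peaks of replicate 2, 1235 (83.1%, 81.1 to 84.9) overlapped a peak of replicate 1. Random placement of the other replicate's peaks on the same chromosomes gave a mean of 0.848% and at most 1.62% for replicate 1, and a mean of 1.00% for replicate 2 (one-sided permutation p = 0.001 for both, the smallest that 1000 placements can give). Each of the 1236 peaks of replicate 1 was paired with the highest overlapping peak of replicate 2, which can enter more than once. Over these pairs the signal values of the replicates had a Spearman correlation of 0.876 and a Pearson correlation of 0.771 on the log2 scale. With summits matched within 100 bp, for 1184 peaks of replicate 1, the correlations were 0.899 and 0.921. These correlations are across peaks, which are not independent replicates. Over all 62173 peaks of replicate 1's ranked list that overlapped one of replicate 2's, the Spearman correlation was 0.273. Of the 2470 pooled peaks, 1240 (50.2%) overlapped a peak of both replicates' lists, with a median signal value of 224, and 585 (23.7%) overlapped a peak of neither, with a median of 82.4.

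**Figure D1:**
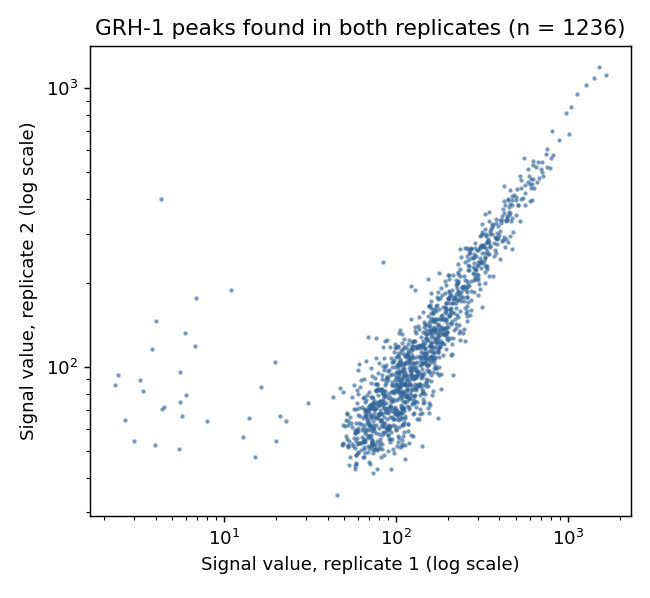
Signal value of replicate 1 (horizontal, log scale) against replicate 2 (vertical, log scale), with 1 point for each of the 1236 peaks of replicate 1 that overlapped a peak of replicate 2. The values rise together (Spearman correlation 0.876), apart from a few loci with a low value in replicate 1. Each peak of replicate 1 was paired with the highest overlapping peak of replicate 2, so a side peak in replicate 1 can give such a point.

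GRH-1 peaks lay at promoters more often than random positions did. Of the 2470 summits, 1337 (54.1%, 52.2 to 56.1) lay from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding transcript, against 25.9% of random positions on the same chromosomes (2.09-fold, two-sided permutation p = 0.001, the smallest that 1000 placements can give). The share was 42.8% with a window from 500 bp upstream to 100 bp downstream and 67.1% with one from 2000 bp upstream to 200 bp downstream. Each base was put in 1 class only, and promoter windows took precedence. The counts and genome shares of the other classes therefore cover only what lay outside those windows. Counted in this way, coding exons held 102 summits (4.13%), although they made up 18.8% of the genome. Introns held 402 summits (16.3%, against 27.5% of the genome), and 535 summits (21.7%) were intergenic, as were 21.7% of the bases. The 3′ UTRs held 13 summits (0.526%), the 5′ UTRs 6 (0.243%) and genes of other kinds 75 (3.04%). The median distance from a summit to the nearest 5′ end was 598 bp, against 1325 bp for random positions, and 71.0% of the summits were upstream of that end. Within 300 bp of a 5′ end lay 36.96% of the summits and 14.2% of the random positions.

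**Figure D2:**
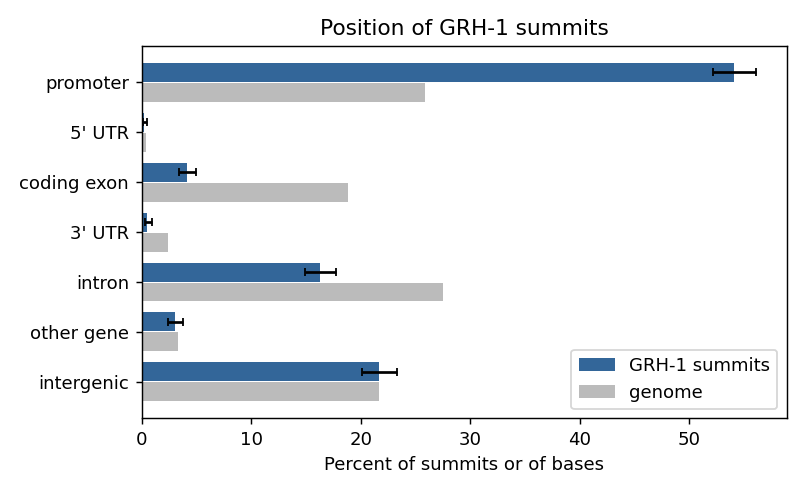
Percent of the 2470 GRH-1 summits (blue, with 95% Wilson intervals) and of the bases of the genome (grey) in each position class. Promoters held 54.1% of the summits and 25.9% of the bases.

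The strongest peak of the genome lay upstream of grh-1 itself. It spanned bases 1273761 to 1274334 of chromosome I, in intergenic sequence, with a signal value of 2830.4 in the pooled list, and its summit was 5800 bp upstream of the outermost 5′ end of grh-1, which lies on the reverse strand between bases 1258201 and 1268155. It ranked 1 in the list of replicate 1 and 2 in that of replicate 2. A protein-coding gene, Y48G8AR.8, lies between the summit and grh-1, and its 5′ end, 2439 bp from the summit, was the nearest. The promoter window of grh-1 held no summit. A second summit, with a signal value of 1122, lay 3007 bp upstream of grh-1 and in the promoter window of Y48G8AR.8, a further one with a value of 476 lay 4469 bp upstream, in an intron of Y48G8AR.8, and one with a value of 88.0 lay 1182 bp upstream. Within 100 bp, the summits with values of 2830.4 and 1122 held none of the Grainyhead-type sites AACCGGTT, AACTGGTT, AACCAGTT and ACCGGT. The summit with 476 held ACCGGT only, and that with 88.0 held AACTGGTT or AACCAGTT only. Regulation of grh-1 from these summits was not tested. The gene grh-1 had been chosen beforehand, while Y48G8AR.8 and the 4 summits were chosen after their values were seen.

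Among the 15 highest-scoring summits, 2 lay in promoter windows of ifbp-1 on chromosome V. The first spanned bases 13371284 to 13371830, with a signal value of 2739, and the other spanned bases 13380131 to 13380583, with a value of 2283 and also within the window of cpz-2. Both held the Grainyhead palindrome AACCGGTT within 100 bp of the summit. Of the summits classed as intronic, and so outside every promoter window, the highest lay in Y48C3A.5 on chromosome II. Its peak spanned bases 13291485 to 13291961, with a signal value of 2127 and a palindrome. Promoter windows of ribosomal protein genes held 3 of the 15, none of which held the palindrome. They were rpl-3 (chromosome III, bases 3867422 to 3867717, signal value 1906), rpl-35 (chromosome III, bases 7854550 to 7854829, 1525) and rpl-20 (chromosome IV, bases 4749933 to 4750215, 1400, shared with Y17G9B.5). The window of Y24D9A.6 held a summit with a value of 2512 and with AACTGGTT or AACCAGTT only. That summit also lay inside ell-1, a gene chosen after its value was seen. The window of cdc-48.1, which encodes an AAA ATPase, held one with a value of 1361 and no Grainyhead-type site. Further intergenic summits among the 15, with values of 1815, 1691, 1360.3, 1339 and 1315, also held none of these sites. The highest summit in a gene that does not code for protein had a value of 1555 and lay on chromosome V between bases 13081107 and 13081631, at a piRNA locus, with a palindrome. Outside promoter windows, the highest in a coding exon lay in pks-1 (641), in a 3′ UTR in C05D11.8 (463) and in a 5′ UTR in C34C12.2 (732).

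Summits were next searched for the palindrome that Grainyhead proteins bind. AACCGGTT occurred within 100 bp of 94 of the 2470 summits (3.81%, 3.12 to 4.63) and in 0.364% of windows of the same width 500 bp to either side, an odds ratio of 10.8 (two-sided Fisher's exact p = 1.12e-28). The sites were centred on the summits: of the 95 sites within 100 bp, 57.9% were within 25 bp, where an even spread would put 25%. The related AACYGGTT, in which Y is C or T, occurred at 8.54% of the summits and in 1.13% of the flanks (odds ratio 8.15, Fisher's exact p = 6.55e-55), and the core ACCGGT at 7.09% and 1.76% (odds ratio 4.25, p = 2.56e-29). Every AACCGGTT site counts for both of these as well, so the 3 results share the 94 summits and are not independent. With ACCGGT only there were 78 summits (3.16%). Of 5 other palindromes made of the same bases, CACATGTG had the highest odds ratio, 3.77. No site of these 3 Grainyhead types was present at 2181 summits (88.3%). Seen from the genome, 95 of the 990 AACCGGTT sites (9.60%, 7.91 to 11.6) were within 100 bp of a summit. That share was 13.5% in promoter windows and 7.86% outside them (odds ratio 1.83, Fisher's exact p = 0.0069), and it was 16.7% for sites with A before and T after the palindrome against 3.85% for sites with neither (odds ratio 5.03, p = 3.51e-07). Both comparisons were added after these data were examined, so their p are not those of tests set beforehand.

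**Figure D3:**
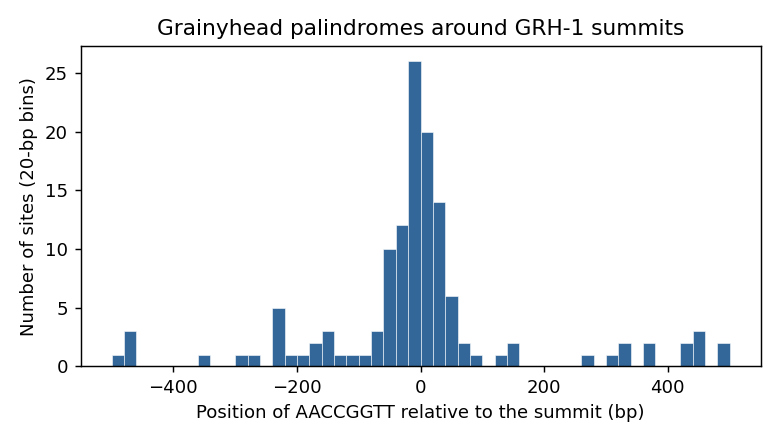
Number of AACCGGTT sites in bins of 20 bp (vertical) by distance from a GRH-1 summit, within 500 bp to either side (horizontal, bp). Of the 132 sites, 95 are within 100 bp of the summit.

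The palindrome went with the height of the peak. With the peaks ranked by signal value and split into groups of equal size, its share was 7.62% in the highest group and 5.02%, 1.62% and 0.971% in those below (Spearman correlation of signal value with presence 0.142, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The median signal value was 225 at the 94 summits with AACCGGTT, 167 at 117 summits with only AACTGGTT or its complement AACCAGTT, 121 at 78 summits with only ACCGGT, and 122 at the summits with none of the Grainyhead types. Down the ranked list, the first 500 peaks held the palindrome at 8.60% and the next 500 at 4.80%, both above their flanks (Fisher's exact test, Benjamini-Hochberg adjusted over all bins, p = 5.61e-14 and 1.33e-06). Of the remaining bins, only that of ranks 1501 to 2000 passed (2.20%, adjusted exact p = 0.0157).

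**Figure D4:**
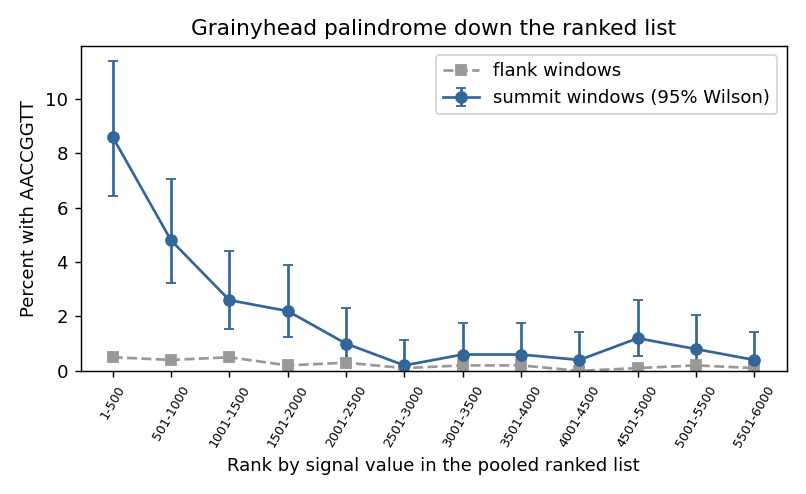
Percent of windows with AACCGGTT (vertical) in bins of 500 peaks down the pooled ranked list (horizontal), at summits (blue, with 95% Wilson intervals) and in flanks (grey). The share falls from 8.60% in the first bin to 1.00% in ranks 2001 to 2500.

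The sequences with the smallest p for enrichment at the summits were of other kinds. In a search of all 32893 8-mers present, 2704 were more frequent at summits than in flanks and 1618 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The first was AGACGCAG, at 12.1% of summits and 1.03% of flanks (odds ratio 13.2, Fisher's exact p = 4.39e-95), followed by its shifted forms GAGACGCA and GACGCAGA and by GAGAGAGA. With all 8-mers ordered by p, whether more or less frequent at summits, the palindrome AACCGGTT ranked 28. The 8-mers that were rarer at summits were led by A and T runs, such as TTTAAAAA (4.90% and 14.6%, odds ratio 0.302). Among the motifs chosen beforehand, the GAGA repeat GAGAGA was at 35.2% of summits and 11.4% of flanks (odds ratio 4.21, adjusted exact p = 1.35e-123) and the E-box CACGTG at 11.1% and 3.64% (odds ratio 3.30, adjusted p = 3.66e-33). Also higher were the RGGTCA site of nuclear receptors (odds ratio 1.74, adjusted exact p = 1.27e-11), the longer NHR-25 site (odds ratio 3.12, adjusted p = 0.016) and, weakly, a RUNX site (odds ratio 1.27, adjusted p = 0.047). Neither the NHR-25 site nor the RUNX site passed with the 1235 highest-scoring peaks (odds ratios 1.67 and 1.26, adjusted exact p = 0.653 and 0.181). Both also failed to pass in the list of replicate 2 and against promoters without a peak. The NHR-25 site was lost as well in the list of replicate 1 and with 50 bp to either side. The RUNX site was lost as well in the conservative list, with merged regions and with 200 bp to either side. The HOX and PBX site was lower (odds ratio 0.766, adjusted exact p = 0.000864). The AP-1, ETS, TEAD, forkhead, GATA and PRDM1-like sites did not pass. The GATA site was lower and passed in 5 alternatives, among them promoters without a peak (odds ratio 0.751, adjusted exact p = 8.20e-05), while with 200 bp to either side its odds ratio was 1.03. The forkhead site was lower and passed in each replicate's own list (odds ratios 0.678 and 0.703), and the PRDM1-like site was higher and passed in the list of replicate 2 (odds ratio 4.02) and with 50 bp to either side of the summit (9.03, adjusted exact p = 0.0034).

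At the level of genes, 1629 of 19973 protein-coding genes (8.16%) had a summit in the promoter window. The 14 gene lists chosen beforehand asked which kinds of genes these were. Genes for ribosomal proteins stood out: 44 of 68 (64.7%, 52.8 to 75) had a summit, against 7.96% of the other genes (odds ratio 21.2, Fisher's exact test adjusted over the lists, p = 2.24e-30). With each summit counted only for the gene with the nearest 5′ end, 22 of 68 genes (32.4%) had one, an odds ratio of 7.32 (adjusted exact p = 8.55e-10). The 43 summits had a median signal value of 223, against 141 at the other promoter summits, and the highest was rpl-15 (953) after the 3 named above. None of the 43 held a Grainyhead site of any of the 3 types (0%, upper limit 8.20%).

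The list of molting and larval timing genes also passed, with 8 of 35 genes (22.9%, 12.1 to 39.0, odds ratio 3.35, adjusted exact p = 0.0432). They included myrf-2 (signal value 423, with a palindrome), the nuclear receptor genes nhr-23 (245), nhr-85 (193) and nhr-25 (186), the heterochronic gene lin-28 (237), which encodes an RNA-binding protein, and myrf-1 (165), a regulator of larval molting. The others, rme-8 (72.1) and lrp-1 (21.6), were chosen after their values were seen, and the summit of lrp-1 lay within 500 bp of a stronger peak. With 1 summit per merged region 7 of 35 genes had a summit, and the list did not pass (odds ratio 2.83, adjusted exact p = 0.146). It also did not pass with the conservative pooled list (odds ratio 2.40, adjusted exact p = 0.39), nor with either replicate's own list (3.53 and 3.55), the 1235 highest-scoring peaks (3.91) or a window of 500 bp (3.06). It passed with each summit counted only for the nearest 5′ end (odds ratio 4.49, adjusted exact p = 0.00796), with a window of 2000 bp (3.35, adjusted p = 0.02), with 1 gene per cluster of list genes within 5000 bp (3.35, adjusted p = 0.0432) and against lists matched on upstream intergenic length (3.50, adjusted permutation p = 0.0245).

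The other epidermal lists did not pass. Of the epidermal transcription factor genes, 4 of 22 had a summit (adjusted exact p = 0.347), namely nhr-23, nhr-25, skn-1 (122) and elt-6 (88.9). In either replicate's own list elt-6 had none. Of the genes for epithelial junctions and polarity, 7 of 42 did (adjusted exact p = 0.347), led by the innexin genes inx-13 (438, with a palindrome) and inx-12 (159), then spc-1 (123) and pkc-3 (115.1). In either replicate's own list 3 of the 42 had a summit (odds ratios 1.08 and 1.32, against 2.26 in the pooled list), and spc-1 had none there. Of the cuticle collagen genes, 14 of 176 (7.95%) had a summit, against 8.16% of other genes (adjusted exact p = 1), and the highest were col-38 (223), col-63 (167), col-95 (151, with a palindrome) and col-71 (144). In the replicates' own lists 8 of 176 collagen genes (4.55%, odds ratio 0.668) had a summit in replicate 1 and 6 of 176 (3.41%, odds ratio 0.601) in replicate 2. The summit of col-38 was also that of rpl-5, whose 5′ end was nearer. The hedgehog-related and patched-related genes had 4 of 87 (adjusted exact p = 0.565), namely ptr-6 (300, with a palindrome), grl-11 (177), wrt-3 (110) and wrt-6 (97.7). Of the epidermal antimicrobial peptide genes, 3 of 22 had a summit (adjusted exact p = 0.652), namely nlp-24 (224), nlp-33 (94.8) and nlp-29 (89.03). Neither replicate's own list nor the conservative list held a promoter summit for nlp-29. The apical extracellular matrix list had 1 of 51, sup-17 (188, with a palindrome, adjusted exact p = 0.350), which encodes a metalloprotease. Over these lists without the antimicrobial peptides, but with the molting genes, 36 of 404 genes (8.91%) had a summit, against a mean of 29.9 in random lists matched on the length of upstream intergenic sequence (95% of lists between 20 and 41).

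Lists of other tissues did not pass either. The counts were 3 of 30 for pan-neuronal genes (snb-1 at 145, ric-19 at 112.03 and snt-1 at 77.7), 2 of 35 for body wall muscle (act-4 at 114 and pat-4 at 74.3), 2 of 41 for the pharynx (peb-1 at 114 and ceh-22 at 100.05) and 3 of 71 for the germline (mex-1 at 172, spn-4 at 102 and spo-11 at 96.1). Among these, snt-1, pat-4 and ceh-22 had no promoter summit in either replicate's own list, and pat-4 also had none in the conservative list. No summit lay at the 30 intestinal genes or at the 9 genes for enzymes of aromatic amino acids, which include bas-1. The summits of col-71, grl-11, mex-1 and spn-4, like that of col-38, lay nearer the 5′ end of another gene, namely Y49F6B.2, ced-11, W03C9.5 and spe-39, which were chosen after their values were seen, as was rpl-5.

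**Figure D5:**
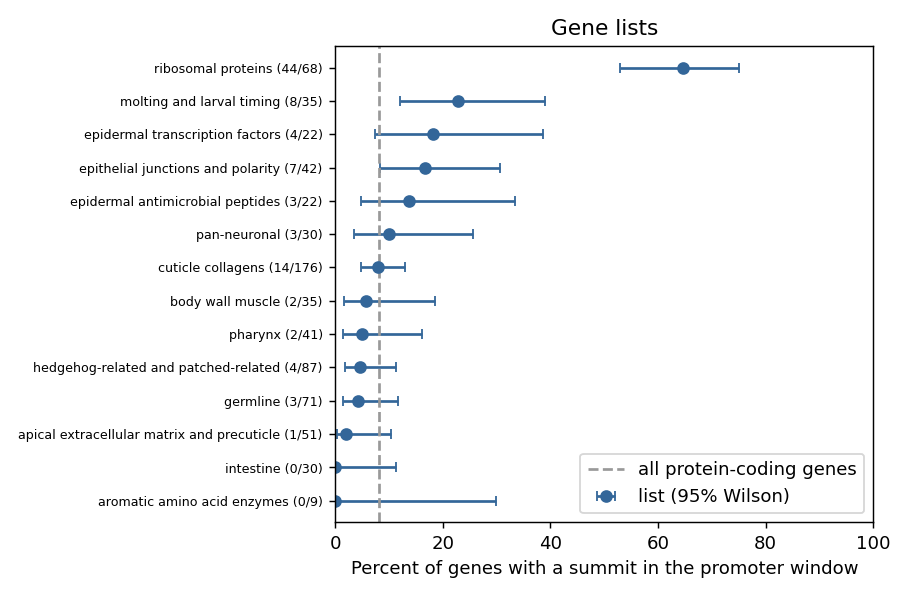
Percent of the genes of each list with a GRH-1 summit in the promoter window (points with 95% Wilson intervals; counts beside the names), and of all protein-coding genes (dashed line, 8.16%). Ribosomal protein genes are at 64.7%, and most other lists have intervals that include the dashed line.

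Of the genes named regardless of their peaks, nhr-23, nhr-25 and myrf-1 had a promoter summit, and grh-1, blmp-1, elt-1, elt-3, lin-26, bed-3, ajm-1, dlg-1, hmr-1, bas-1 and lin-42 did not. Some of these had summits elsewhere. A summit with a value of 590 lay upstream of the promoter window of blmp-1, one with 236 in an intron of lin-42, one with 82.3 in an intron of hmr-1, and one with 203 within 5000 bp of lin-26, in an intron of the neighbouring lir-1 locus. No summit lay within 5000 bp of elt-1, elt-3, bed-3, ajm-1, dlg-1 or bas-1 in the pooled list. The conservative list placed a summit in the promoter window of dlg-1.

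Summits were spread unevenly over chromosomes. Chromosome V held 421 (17.04% of summits and 20.9% of the genome, two-sided binomial test adjusted over 6 chromosomes, p = 1.17e-05), and chromosome III 393 (15.9% and 13.7%, adjusted p = 0.00644), which did not pass in replicate 2's own list (15.7%, adjusted p = 0.103). Chromosome IV held 384 (15.5% and 17.4%, binomial test, adjusted p = 0.019), which did not pass in either replicate's own list (adjusted p = 0.224 and 0.103). With promoter summits set against promoter bases its share was 15.4% and 17.2%, which did not pass either (binomial test, adjusted p = 0.117). The X chromosome held 489 (19.8%, 18.3 to 21.4, against 17.7% of the genome, binomial test, adjusted p = 0.0122), but with promoter summits set against promoter bases its share was 16.4% and 14.8% (adjusted p = 0.117), and in the replicates' own lists it did not pass.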

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

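The test in this part was chosen after the result was seen. The Grainyhead palindrome was enriched in the highest peaks outside the pooled thresholded list, which the comparisons of bound positions did not use. Among the 5000 highest peaks of the pooled ranked list that lay over 1000 bp from any thresholded summit, 28 (0.560%, 0.388 to 0.808) held AACCGGTT, against 0.150% of their flanks (odds ratio 3.75, two-sided Fisher's exact p = 2.61e-05). In the next 5000 such peaks the shares were 0.300% and 0.210% (Fisher's exact p = 0.292). Over all 111790 such peaks they were 0.218% and 0.173% (odds ratio 1.26, Fisher's exact p = 0.00523). Leaving out the peaks that had an IDR of at most 0.01 but were not listed lowered the highest signal value of the 5000 from 1594.5 to 174. It left 28 with the palindrome and an odds ratio of 3.75, so the enrichment was present without those peaks. Only 49 such peaks were in the whole ranked list, so their removal could change little and says little about other sources. In the 5000 highest peaks outside the thresholded list, AACYGGTT was at 1.98% against 0.92% of flanks (odds ratio 2.18). The unrelated GACGCAG was at 4.40% against 1.52% (odds ratio 2.98), so enrichment there was not particular to Grainyhead sites. The control palindromes were not examined in these peaks, so base composition was not tested there. Which of these peaks are bound stays open, and no biological explanation was tested.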

How the results depend on the processing

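Of the alternatives, those without the peaks under a signal value of 30, those for the 7-mer GACGCAG, the added antimicrobial peptide list and the summed palindromes were chosen after the data were seen; the others were set before. No result that passed its threshold changed direction under the alternatives run, while some odds ratios that did not pass crossed 1, such as those of epithelial junctions (0.942, highest-scoring peaks), pan-neuronal genes (0.589) and antimicrobial peptides (0.814, both without replicate 1), the GATA site (1.03, 200 bp) and ACCATGGT (0.571, without replicate 2). Among values that answer a comparison, 188 alternatives kept their side of the threshold or stayed within their spread, 18 moved further, 10 no longer passed and 1 came to pass; for single motifs and genes the counts were 340, 53, 15 and 9. The share with AACCGGTT ranged from 2.92% to 6.32% over settings of that site and passed in each, and the promoter share (42.8% to 67.1%) was above random placement in each. The odds ratio of AACCGGTT was 6.74 with 200 bp to either side and 16.6 for the highest-scoring peaks, against 10.8 in the main setting. The number of peaks was 1235 for the highest-scoring peaks and 1487 to 1787 with a replicate left out. Replicate overlap fell to 61.2% and 73.8% with 50% reciprocal overlap and to 66.3% and 79.6% with summits within 100 bp, as stricter rules count fewer pairs. The signal correlation was 0.273 over the ranked lists and 0.899 for matched summits. The count of higher 8-mers was 1561 for the highest-scoring peaks and 1247 against promoters without a peak, and that of the other motifs was 5 in both, against 8. The number of lists that passed was 1, against 2, with the conservative list, a replicate left out (1 to 1), the highest-scoring peaks, merged regions and the 500 bp window. The list lost was molting and larval timing, with odds ratios of 2.40 (conservative), 3.53 to 3.55 (a replicate left out), 3.91 (highest-scoring), 2.83 (merged) and 3.06 (500 bp window), and adjusted p from 0.0510 to 0.390. Epidermal transcription factors passed with the 2000 bp window (3.90, adjusted exact p = 0.0297). The share on X was 18.9% to 19.4% with a replicate left out, 18.7% for the highest-scoring peaks and 16.4% for promoter summits, none of which passed, while it passed in the conservative list and merged regions. The cause of these changes was not tested. Of 53 named genes, 42 had a promoter summit in the pooled list, 40 in the conservative list, 34 in replicate 1 and 30 in replicate 2. No paired comparison of samples was possible because there was only 1 group. Each summit was also paired with its own flank 500 bp towards higher coordinates. AACCGGTT was only at the summit in 93 pairs and only in the flank in 9 (exact McNemar test, p = 9.98e-19). Unknown read depth limits what the absence of a summit says.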

Other observations

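Chosen only after results were seen were the tests on gene families, genes that do not code for protein, chromosome regions, GACGCAG, sites that occur together, single changes to the palindrome, promoter share by site, summed palindromes, nearest genes by site and ribosomal protein promoters; the gene families and genes they name were chosen after their values were seen. Over 175 families of at least 10 protein-coding genes that share a name, the large and small ribosomal subunit families led, with a promoter summit at 30 of 47 rpl genes (63.8%) and 21 of 31 rps genes (67.7%) by name. Other families that passed included 11 of 29 dnj chaperone genes (37.9%, Fisher's exact test adjusted over the families, p = 0.000391), 14 of 47 genes named lin (29.8%, adjusted p = 0.000498), 17 of 72 histone genes (23.6%, adjusted p = 0.0015), 9 of 26 npp nucleoporin genes (34.6%, adjusted p = 0.00238) and 7 of 20 vha genes of the vacuolar ATPase (35.0%, adjusted p = 0.0104). Chemoreceptor genes were rarely bound, with 1 of 193 str genes (adjusted exact p = 0.00012) and 4 of 220 srh genes (adjusted p = 0.00225), and the C-type lectin genes had 5 of 240 (adjusted p = 0.00225). Summits lay within 200 bp of a tRNA gene at 3.32% against 0.259% of random positions (odds ratio 13.2, Fisher's exact test, adjusted p = 6.86e-52), of a snoRNA gene at 2.75% against 0.150% (odds ratio 18.9, adjusted p = 1.56e-50) and of a snRNA gene at 1.26% against 0.0668% (odds ratio 19.01, adjusted p = 7.36e-24), and none of the summits at these 3 classes held AACCGGTT. Genes annotated as ncRNA were near 15.3% of summits against 3.59% of random positions (odds ratio 4.86, adjusted exact p = 4.00e-112), and 2.12% of those summits held AACCGGTT, while piRNA genes (0.931% against 2.88%) and pseudogenes (0.972% against 3.83%) were less often near summits. The middle 50% of the chromosome held 72.4% of the summits (67.99 to 76.5) on V, 60% on II, 55.6% on I, 55.2% on III, 50.5% on IV and 49.5% on X.

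The 7-mer GACGCAG was at 326 summits (13.2%, 11.9 to 14.6) and 1.64% of flanks, and its share was 13.2% to 15.7% over the peak lists examined. Split into groups of equal size by signal value, the peaks held it at 17.3% in the highest group and 8.90% in the lowest. It was less frequent at summits with a Grainyhead site of the 3 types (4.50%) than at the others (14.4%, odds ratio 0.281, adjusted exact p = 2.42e-06), and AACYGGTT summits were less often at promoters (44.1%) than the others (55.1%, odds ratio 0.643, p = 0.00238). Of the single changes to the palindrome, AACCAGTT (odds ratio 6.41), AACCGGTC (5.51) and AACAGGTT (4.36) passed adjustment over the 12 sequences.

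The first pattern weighed is the palindrome at the summits. Base composition was tested with the 5 palindromes of the same bases, of which the highest odds ratio was 3.77 (95% exact interval 1.496 to 10.3) against 10.8 (6.47 to 19.1) for AACCGGTT, and with 50 bp to either side CAACGTTG reached 8.01 on 4 summits (0.792 to 395) against 14.6, so single palindromes were too rare to decide. Summed, the 5 had an odds ratio of 2.56 (1.66 to 3.97), which argues against base composition as the whole of the enrichment. Keeping 1 summit per merged region left 2355 summits, all 94 with the palindrome among them, and an odds ratio of 10.8. None of the 94 was therefore a lower peak of a merged region. Few summits were removed, so the odds ratio could hardly have fallen far. Binding of GRH-1 to the palindrome is a hypothesis for the 94 summits that hold it, as no untagged sample was analysed here.

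The second pattern is the large number of summits without AACCGGTT, among them those at ribosomal protein promoters. Of the genes with a palindrome summit 5 of 41 (12.2%, 5.32 to 25.5) were in the epidermal lists (col-95, inx-13, myrf-2, ptr-6 and sup-17), against 31 of 1588 genes (1.95%) with other summits only and 2.01% of genes without a summit (odds ratio of other against palindrome summits 0.143, Fisher's exact p = 0.00167). This is consistent with a different binding event, or another source of signal, at the other summits. The share of ribosomal protein summits with a Grainyhead site was 0% of 43, against 9.51% of 1294 other promoter summits (odds ratio 0.109, Fisher's exact p = 0.0281), which argues against such sites as the route there, although GAGAGA (13.95% against 33.1%, p = 0.00756) and CACGTG (0% against 9.81%, p = 0.0291) were lower there too, so the lack of sites was not particular to Grainyhead sites. Strong promoters without a site remain open, from that same comparison, as do indirect binding and signal at open chromatin, which were not tested, and no biological explanation beyond these comparisons of sites and gene lists was tested.

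The third pattern is a set of 86 thresholded peaks with a signal value under 30. All 86 (100%, 95.7 to 100) lay within 500 bp of a thresholded peak with a higher value, against 1.38% of the 2384 others, and none held AACCGGTT. A low value leaves more peaks that can be higher, so part of the contrast with the others follows from the ranking. That all 86 had a stronger peak so near goes with side peaks of stronger ones. No biological explanation was tested.

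The epidermal lists together did not stand apart, as 1413 of 10000 random lists matched on upstream intergenic length had as many genes with a summit as the 36 observed, and 1040 did with the antimicrobial peptides added. With those peptides added, a set that was examined first although the test had named 6 lists, the odds ratio of other against palindrome summits was 0.158 (Fisher's exact p = 0.00241).

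Whether the 5 epidermal genes with a palindrome summit are too few to carry a pattern stays open, because at 59 genes with only AACTGGTT or AACCAGTT the odds ratio against genes with none was 1.91 (95% exact interval 0.214 to 7.90, p = 0.303), which includes both 1 and the 7.54 of AACCGGTT. For the 36 genes with only ACCGGT the odds ratio was 3.19 (0.354 to 13.6), on 2 genes. By nearest 5′ end, 9 of 94 palindrome summits (9.57%) were at epidermal list genes against 3.03% of summits with none of the sites (odds ratio 3.39, Fisher's exact p = 0.00313). With only AACTGGTT or AACCAGTT 4 of 117 (3.42%) were (odds ratio 1.13, Fisher's exact p = 0.78). With only ACCGGT 5 of 78 (6.41%) were (odds ratio 2.19, Fisher's exact p = 0.0956). A p of 0.05 or more had been set beforehand to speak for chance, and the reading that 2 genes are too few to decide was added after the value was seen.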
